A study of Mus musculus with 2 samples.

How the data were processed

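The samples were 2 pools of 30 Purkinje cells each, the large output neurons of the cerebellar cortex, taken from tissue by laser capture from adult male mice aged 14 months. Per the labels, the animals were B6CASTF1/J, the first-generation cross of a C57BL/6 and a CAST strain, total RNA in a size range above 200 was used, and complementary DNA was made with a SMARTer Ultra Low kit and sequenced on Illumina HiSeq instruments. Both pools carried spike-in RNA. The labels number the pools as biological replicates 1 and 2 and give both the same donor identifier. They do not say whether both pools came from a single animal, so a standard deviation (SD) here measures only the spread between these pools, which may be technical.

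The deposited tables were made per library against mouse genome build mm10 (GRCm38) with GENCODE annotation M4, per the text file deposited with each sample. Bias towards the C57BL/6 allele, which that reference could give in reads of the cross, was not tested and limits the levels printed. The column names are those that RSEM writes. The aligner, the quantifier and their versions are not given in the sources used here. Per the file headers, each deposited table holds expected counts, which are estimated reads per gene or transcript and need not be whole. The deposited TPM values, transcript abundances corrected for effective length, sum to 1000000 in each library over all rows, spike-ins included. The deposited FPKM values, fragments scaled by length and depth, and posterior mean values of each kind were used only as alternatives. Per the file headers, the deposited transcript tables also give the percent of a gene's TPM in each transcript. The interval bounds on TPM in the deposited tables were not used, since their level is not given in the sources used here. In 100% of the transcripts longer than 99 bases the deposited effective length was the length minus 99, so TPM of short transcripts is raised steeply per read.

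Each gene table held 69691 rows, of which 43346 had Ensembl gene identifiers, 96 were spike-in transcripts of the ERCC set, 1 was the phiX control genome and 26248 had numeric identifiers. Symbols, gene types and coordinates came from GENCODE M21 on the same build, a later release than the authors used, and 42462 of the identifiers matched a symbol. The rows with numeric identifiers name no gene and were left out of library sizes and tests. They held 0.000412% of counts in pool 1 and 0.000194% in pool 2. Spike-ins were left out of gene counts and tests and analysed separately.

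The totals were 31503819 expected counts in pool 1 and 28709397 in pool 2. Reads carried no molecular identifiers as far as the labels say, so binomial intervals (exact, 95%) cover counting error only. Expected counts were rounded to whole numbers for count models.

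A gene was counted as detected at a TPM of at least 1. Correlations across genes used log2(TPM + 1) of genes detected in at least 1 pool. The biological coefficient of variation came from the common dispersion of edgeR 4.0.16 (estimateDisp, intercept only, TMM scaling) over genes with at least 10 counts in both pools. With 1 group there was no contrast to test. Each gene with at least 10 counts in total was compared between the libraries with a two-sided exact binomial test given the TMM-scaled totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares these libraries, not conditions. Fixed gene lists, 25 in number with 298 genes and 10 of them marker lists of cell types, were described by the median of mean log2(TPM + 1), placed among 10000 random lists of the same size drawn from protein-coding genes. The shift of a list was the median log2 ratio of TPM + 1, pool 2 over pool 1, of its members detected in at least 1 pool. It was placed among 10000 random lists matched on level in 20 bins. Lists with fewer than 3 detected members had no shift. Shifts were also computed from count ratios under each scaling. Fold changes on the log2(TPM + 1) scale understate changes of low genes.

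Spike-in agreement was the SD of the log2 ratio over spike-ins with at least 10 counts in total, set against genes of the same counts. The dominant transcript was the highest by TPM, over genes at a TPM of at least 10 in both pools with at least 2 annotated transcripts.

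The genes named in the text were set by a rule: the 4 highest detected members of each list, or 2 for cell types other than Purkinje cells; Purkinje list members under a TPM of 1 in both pools; the 15 nuclear genes with the highest mean TPM; the 5 genes with the largest count ratio in each direction past the threshold with a mean of at least 100 counts; all sex-linked genes; and, for transcripts, the 5 highest Purkinje list members. The rule, these lists, the tests and the alternatives, apart from those said to be later, were fixed before the data were examined. Genes named outside the rule are said to be so, and some genes that the rule names are not reported here. Genes with near-identical copies, and overlapping genes on opposite strands, were read with caution, since the labels state no strand-specific counting.

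The comparison of the libraries, the dispersion and the list shifts were tested on simulated data, and the other calculations were not. For the comparison of the libraries over 14482 genes, 67.0% of 100 genes changed 1.5-fold and 100% of 100 genes changed 3-fold were recovered, with 7 false calls among 14282 unchanged genes. For the dispersion, counts made with coefficients of 0.200, 0.400 and 0.800 gave 0.198 over 12686 genes, 0.387 over 12359 and 0.716 over 11037. For the list shifts over 8958 genes, 6 of 100 random lists of 12 genes fell outside the central 95%, as did 20 of 20 lists moved by 1 on the log2 scale. Alternatives were other scalings (DESeq2 1.42.0 size factors, total counts, spike-in totals), thresholds, pseudocounts, FPKM, posterior means, TPM rescaled without mitochondrially encoded genes and spike-ins, and each pool alone. A rescaling that also left out pseudogenes of mitochondrial genes and the Malat1 locus was chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.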

Results

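RNA of 2 laser-captured pools of 30 mouse Purkinje cells was profiled, and the deposited tables held 31503819 expected counts for pool 1 and 28709397 for pool 2. The pools form a single group, so the data describe which genes the captured material carried, how far it held other cell types, and how far the pools agreed. All mean values are over the pools, with the SD between them (n = 2). Coordinates are on mouse build mm10.

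The transcripts highest in the pools included known Purkinje cell genes together with a nuclear RNA and mitochondrial sequence. Gng13, a G protein gamma subunit (identifier ENSMUSG00000025739.9, chromosome 17, 25717171 to 25719406), had a mean TPM of 38512 ± 1326 (SD, n = 2). Pcp4, a calmodulin-binding peptide (ENSMUSG00000090223.1, chromosome 16, 96467606 to 96525793), had 25537 ± 1651, and Pcp2, a Purkinje cell regulator of G protein signalling (ENSMUSG00000004630.14, chromosome 8, 3623371 to 3625545), had 16995 ± 989. Calb1, which encodes the calcium buffer calbindin (ENSMUSG00000028222.2, chromosome 4, 15881264 to 15908064), had 2239 ± 248. Of 19 genes on the Purkinje cell list, 17 were at a TPM of at least 1 in both pools. The list's median of log2(TPM + 1) was 7.77 ± 0.01 (SD, n = 2), above all 10000 random lists of protein-coding genes. The only member under a TPM of 1 in both pools was Skor2, a transcriptional corepressor, with 0.06 and 0.14 from 7 and 15 counts. The transcription factors Lhx1 (7.60 ± 0.297) and Foxp2 (3.04 ± 0.177) and the glutamate transporter Slc1a6 (17.7 ± 8.58), named here after their values were seen, lay far below the list's median.

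Among markers of other cerebellar cell types, those of Bergmann glia were high in both pools, and most other lists had medians far below that of the Purkinje list. The Bergmann glia and astrocyte list had a median of 6.07 ± 0.90 (SD, n = 2), above all 10000 random lists, with 12 of 13 members detected in both pools. Its highest members were Slc1a3, a glial glutamate transporter (ENSMUSG00000005360.10, chromosome 15, 8634124 to 8710764), at a TPM of 1804 ± 699, and Gja1, which encodes the gap junction protein connexin 43 (ENSMUSG00000050953.9, chromosome 10, 56377330 to 56402513), at 622 ± 311. The median was 1.79 ± 0.10 for the granule cell list, with 9 of 15 members detected in both pools. It lay at percentile 99.1 among random lists of protein-coding genes and 22.8 among lists of detected genes. Its highest members were the transcription factors Zic1 (10.5 ± 1.89) and Neurod1 (9.16 ± 2.51). The median was 0.54 ± 0.13 for inhibitory interneurons (2 of 9 members), whose highest were the kinase gene Prkcd (19.7 ± 2.45) and the receptor Kit (2.00 ± 0.537). It was 0.89 ± 0.05 for oligodendrocytes (4 of 11), led by the myelin genes Cnp (26.6 ± 8.85) and Mbp (9.10 ± 2.52).

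Oligodendrocyte precursor markers had a median of 0.01 ± 0.01 (1 of 6 detected in both pools, the transcription factor Olig1 at 1.70 ± 0.148). Microglial markers had 0.46 ± 0.04 (2 of 12), among them the adaptor Tyrobp at 1.67 ± 0.785. Endothelial and mural markers had 0.25 ± 0.04 (3 of 13), with Ly6c1 at 12.8 ± 2.74 and Vtn at 2.67 ± 1.56. Choroid plexus and ependymal markers had 0.15 ± 0.02 (0 of 6). The red blood cell list had 5.85 ± 4.99 (4 of 5), a mean over pools that lay far apart. The Purkinje list's median was above that of the red blood cell list by 1.92 over both pools and below it in pool 1 alone.

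**Figure D1:**
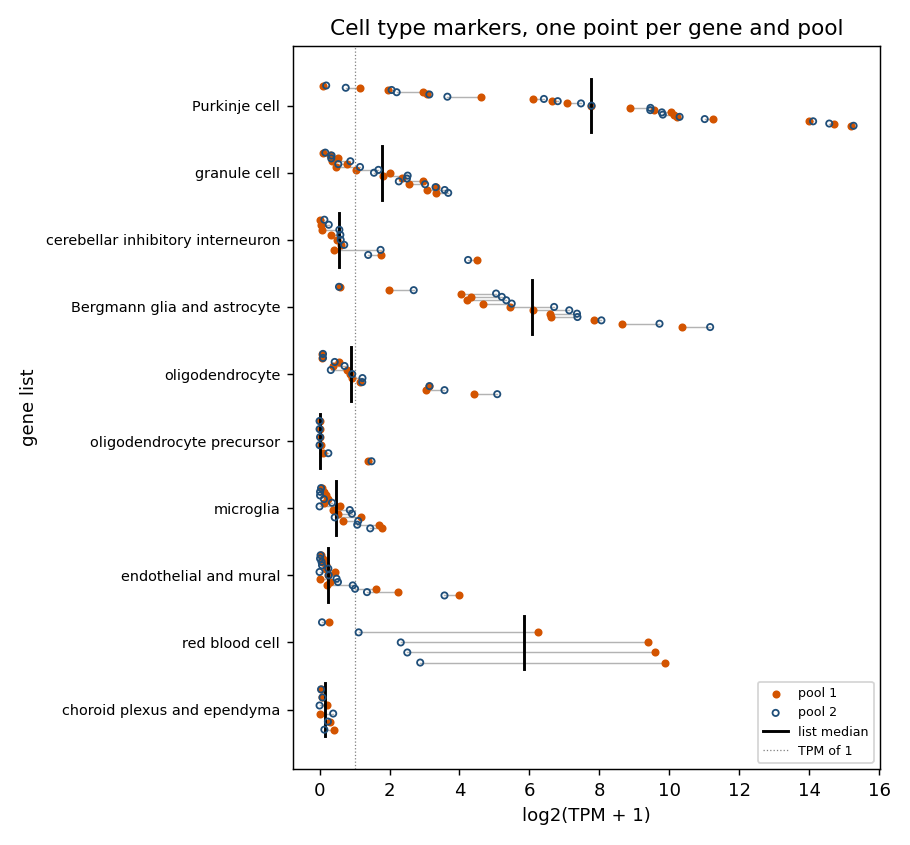
Level of each marker gene as log2(TPM + 1) on the x axis, by cell type list on the y axis; filled points are pool 1, open points pool 2, grey lines join the pools, and black bars are list medians. Over both pools the Purkinje list's median of 7.77 is the highest and the Bergmann glia and astrocyte list follows at 6.07, but in pool 1 alone the red blood cell list is higher, at 9.38, against 2.32 in pool 2.

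All 11 members of the list of glutamate and calcium signalling genes were detected in both pools, with a median of 5.65 ± 0.11 (SD, n = 2), above all 10000 random lists. Itpr1, the calcium release channel gated by inositol trisphosphate, had a TPM of 973 ± 128 and the G protein regulator Rgs8 had 105 ± 8.87. Of 22 calcium buffering and handling genes, 12 were detected in both pools and 10 were under a TPM of 1 in both (median 2.15 ± 0.25). The highest included the buffer Pvalb (8017 ± 782), the calmodulin gene Calm2 (7428 ± 1115) and Calb1.

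Of 16 GABA-A receptor subunits 8 were detected in both pools (median 1.35 ± 0.44), among them Gabra6 (8.98 ± 0.0212) and Gabrb1 (4.45 ± 2.95). Of 18 ionotropic glutamate receptor subunits 9 were detected (median 1.01 ± 0.20), among them the AMPA receptor subunits Gria2 (58.4 ± 1.34), Gria3 (22.6 ± 0.304) and Gria4 (21.5 ± 10.7). Of 8 metabotropic glutamate receptors (median 0.69 ± 0.20), 3 were detected in both pools, among them Grm3 at 5.99 ± 2.85 and Grm7 at 3.78 ± 1.01. Gria2 exceeded Gria3 by more than the SD between pools, and Gria3 and Gria4 were not separated by it. Gabra6 is also on the granule cell list. The log2 ratio of TPM + 1, pool 2 over pool 1, was 1.16 for Gabrb1, 1.01 for Gria4 and 0.86 for Grm3. It was 0.44 for Grm7, -0.05 for Gria2, -0.03 for Gria3 and -0.004 for Gabra6. The Bergmann glia and astrocyte list had 0.85. Which cells in the pools held these transcripts was not tested.

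Channel subunits were mostly low. Among 13 sodium channel subunits were the beta subunit Scn2b (15.6 ± 4.46) and the pore-forming Scn1a (12.7 ± 1.82) and Scn8a (7.42 ± 0.191), and 6 were detected in both pools (median 0.42 ± 0.03). Among 18 calcium channel subunits, 5 were detected (median 0.26 ± 0.04), with Cacnb4 at 13.8 ± 0.467, the T-type Cacna1g at 11.8 ± 1.31, the P/Q-type Cacna1a at 5.29 ± 0.898 and Cacna2d2 at 5.12 ± 0.962. Of 25 potassium and HCN channel genes, 11 were detected (median 0.58 ± 0.16). Kcnma1, the large-conductance calcium-activated channel, had 23.2 ± 2.92, the small-conductance Kcnn2 had 13.5 ± 7.58, Kcna1 had 10.9 ± 1.15 and the beta subunit Kcnmb4 had 9.53 ± 2.04. Scn2b and Scn1a differed by less than the SD between pools, so these were not ordered.

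Among transmitter genes, those of GABA were the highest. Gad1, which makes GABA (chromosome 2, 70553072 to 70602014), had a TPM of 657 ± 25.04 and the GABA-degrading Abat had 54.3 ± 7.73. Tyrosine hydroxylase, Th, had 26.0 ± 7.21. Of the 13 genes on that list, 6 were detected in both pools (median 0.46 ± 0.09). The vesicular glutamate transporters Slc17a6, Slc17a7 and Slc17a8, named after their values were seen, had 0.0300, 0.255 and 0 TPM.

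**Figure D2:**
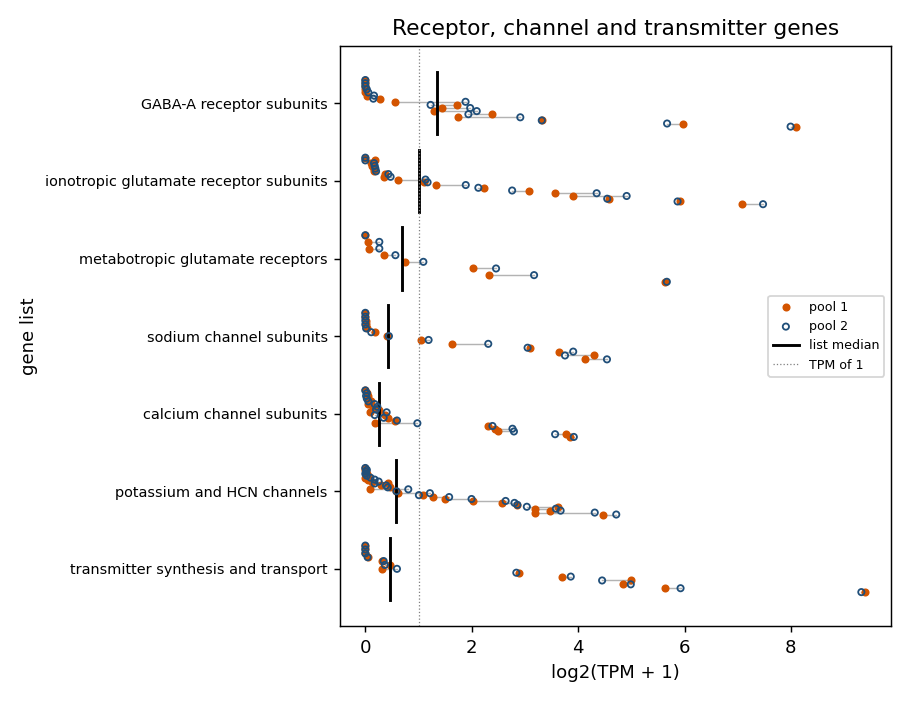
Level of each receptor, channel and transmitter gene as log2(TPM + 1) on the x axis, by list on the y axis; filled points are pool 1, open points pool 2, grey lines join the pools, and black bars are list medians. A few members of each list stand apart, among them Gad1 (TPM 657) and Gria2 (58.4).

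Genes linked to zebrin, the banded pattern of Purkinje cells, included markers of both band types. Aldoc, the zebrin antigen and also a glial gene (chromosome 11, 78322968 to 78327781), had a TPM of 16972 ± 1638 (SD, n = 2), Kctd12 had 136 ± 15.7, the GABA-B receptor Gabbr2 had 55.1 ± 4.16 and Plcb4, a phospholipase of zebrin-negative bands, had 45.0 ± 13.2. All 7 members were detected in both pools (median 5.49 ± 0.38). Of 24 hereditary ataxia genes 19 were detected in both pools (median 3.20 ± 0.08, above all 10000 random lists), led by Car8, a regulator of Itpr1 (1228 ± 38.1), and Itpr1. Immediate early and stress genes were near the detection limit (median 0.22 ± 0.04), and of 14 only the phosphatase Dusp1 (1.45 ± 0.424) was at a TPM of at least 1 in both pools.

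Y-linked genes had counts in both pools, which the labels call male. Ddx3y (11.96 ± 1.94), Eif2s3y (11.3 ± 0.332), Uty (1.89 ± 0.481) and Kdm5d (0.915 ± 0.460) were measured, while Xist, the RNA of the inactive X, had 12 and 3 counts. Sex-linked genes as a list had a median of 1.52 ± 0.24. Housekeeping genes had a median of 7.35 ± 0.19, with the actin gene Actb at 18605 ± 2600, Ppia at 4565 ± 98.4, Gapdh at 800.3 ± 84.8 and Eef1a1 at 261 ± 58.6, several of which have many processed pseudogenes.

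Mitochondrial and nuclear non-coding sequence took a large share of the reads. Mitochondrially encoded genes held 8.63% of counts in pool 1 and 8.04% in pool 2, and all 13 mRNAs were detected (median 12.19 ± 0.10). The highest by TPM were mt-Atp8 (17233 ± 1692), mt-Nd1 (13493 ± 576), mt-Cytb (11996 ± 1013) and mt-Atp6 (9471 ± 1741), subunits of ATP synthase and the respiratory chain. The TPM of mt-Atp8 is raised by its short length. It had 78593 and 58893 counts in pools 1 and 2, against 539552 and 412249 for mt-Cytb. A further 11.99% and 11.7% of counts lay on 5 pseudogenes of mitochondrial genes on chromosome 1, among them Gm28437 (51848 ± 2116), Gm10925 (41309 ± 537), Gm28661 (39178 ± 2675) and Gm29216 (27577 ± 980). Those pseudogenes share nearly all their sequence with mitochondrial transcripts. The levels of the pseudogenes and of the mitochondrial genes they match are therefore uncertain, as are the order and total share of the mitochondrial genes. Malat1, a nuclear long non-coding RNA (chromosome 19, 5795690 to 5802672), had 74346 ± 24734 and Gm37376, on the opposite strand within it (5801941 to 5802393), had 55604 ± 20073. Reads of that pair cannot be assigned by strand, and together they held 8.11% of counts in pool 1 and 4.63% in pool 2. The other nuclear genes among the 15 highest were the metallothionein Mt1 (15172 ± 5327), Dbi, an acyl-CoA-binding protein (14801 ± 4151), the cytochrome oxidase-associated Ndufa4 (12401 ± 363) and the identifier ENSMUSG00000045999.9 (9495 ± 5779), which matched no symbol.

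At a TPM of at least 1, 7631 genes were detected in pool 1 and 8421 in pool 2, a mean of 8026 ± 559 (SD, n = 2). Of these, 7094 were detected in both, which was 79.2% of the 8958 detected in either. Lower thresholds raised the count to 13858 at a TPM of at least 0.1, and a TPM of at least 5 left 3659. Levels correlated across those 8958 genes with Pearson's r = 0.961 and Spearman's rho = 0.888, computed across genes, which are not independent replicates. The SD of the log2 ratio was 0.59 for the 5640 genes with a mean TPM from 1 to 10, 0.56 for 1849 genes from 10 to 100, 0.71 for 481 genes from 100 to 1000 and 0.31 for 126 genes above. The range from 100 to 1000 holds the globin genes Hbb-bs, Hba-a1 and Hba-a2, with log2 ratios of -6.99, -7.09 and -7.06, which raise its SD. The share of genes within 2-fold rose with level, at 89.4%, 91.5%, 95.8% and 99.2%. On the TPM scale the median log2 ratio of all detected genes was 0.24, against 0.04 for TMM-scaled counts, so shifts are read against these values.

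**Figure D3:**
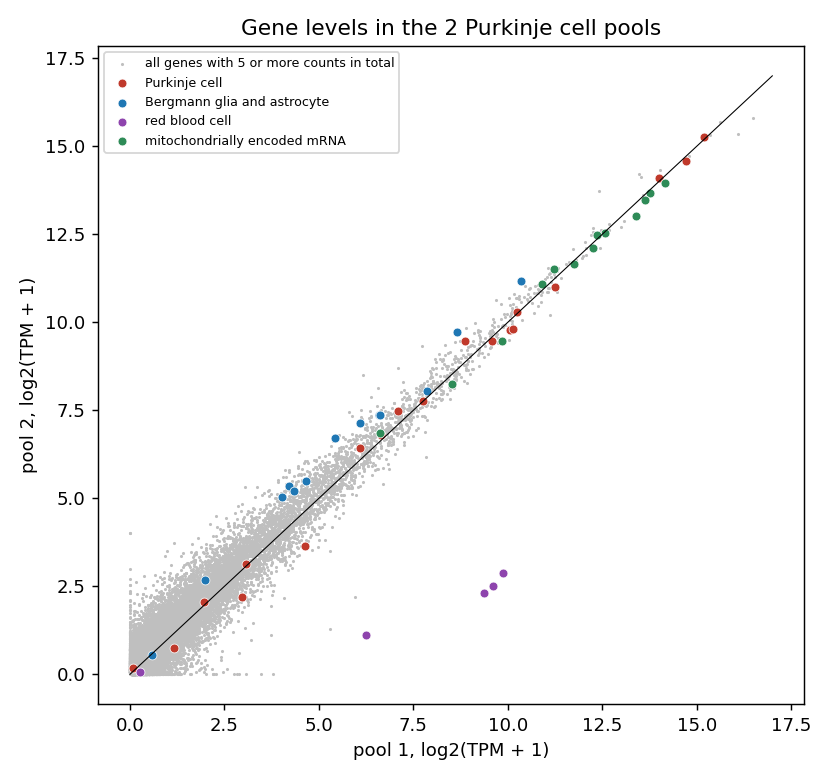
Level of each gene in pool 1 (x axis) and pool 2 (y axis), both as log2(TPM + 1), with the line of equal levels; grey points are genes with 5 or more counts in total and colours mark 4 gene lists. Most genes lie along the line (Pearson's r = 0.961 over detected genes), Bergmann glia markers lie above it on this scale (their median is negative under spike-in totals, which move all genes alike, and 0.63 relative to all detected genes), and 4 globin genes lie far below it.

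The pools differed by more than read sampling. Of 14495 genes with at least 10 counts in total, 9431 (65.1%) differed at an adjusted p under 0.05 in the exact binomial test, which compares these libraries and not conditions. Of these, 4847 were higher in pool 2 and 4584 in pool 1, and 4174 differed by more than 2-fold. The median chi-square per gene was 10.6, against 0.455 for sampling alone, so the tables do not hold the same library deposited again. That comparison does not tell separate samples from separate amplifications of the same material. The split of calls depended on the scaling, with 51.4% higher in pool 2 under TMM, 64.4% under total counts and 14.3% under spike-in totals. The biological coefficient of variation was 0.371 over 11849 genes and ran from 0.467 at the 10th percentile of level to 0.2502 at the 90th. It was 0.572 with no filter on low counts. The square root of the median of DESeq2's gene-wise dispersions, which is a different statistic, was 0.209.

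Haemoglobin and Bergmann glia genes stood out between the pools. Hbb-bs, the adult beta globin (chromosome 7, 103826534 to 103828096), had a TPM of 936 in pool 1 and 6.35 in pool 2, Hba-a1 had 776 and 4.69, Hba-a2 had 666 and 4.00 and Hbb-bt had 75.2 and 1.17. Those are near-identical copies within each globin pair, so the split among copies is uncertain. The median log2 ratio of the 4 detected red blood cell genes was -7.03 (percentile 0 among matched random lists) and stayed negative under every scaling run. All 12 detected Bergmann glia and astrocyte genes had higher TPM in pool 2, with a median log2 ratio of 0.85 (above all matched random lists, whose central 95% was -0.10 to 0.47). Hopx, named after its values were seen, had the lowest of these ratios at 0.20, below the 0.24 of all detected genes. It had 9543 counts in pool 1 and 9438 in pool 2. Slc1a3 had a TPM of 1309 to 2298 and Gja1 401 to 842, from pool 1 to pool 2. Under spike-in totals the glial median turned to -0.10, against -0.74 for all detected genes, while it was 0.68 under TMM, against 0.04. A scaling moves all genes alike, so the difference from all detected genes, 0.63 in count ratios, does not depend on it by construction.

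The Purkinje list had a median log2 ratio of 0.04 (percentile 15.6), against 0.24 for all detected genes, with 10 of 18 members higher in pool 2. The median of its count ratios was negative under every scaling run, at -0.23 under TMM, -0.20 under DESeq2 size factors, -0.04 under total counts and -1.01 under spike-in totals, which is -0.27 relative to all detected genes. Endothelial and mural markers, with 3 detected, had a median of -0.59 on the TPM scale (percentile 1.30), -1.27 in TMM-scaled count ratios and -0.01 with no filter on low values. Microglial markers, with 4 detected, had -0.48 (percentile 2.75), and -1.01 in TMM-scaled count ratios. The remaining fixed lists with a shift lay within the central 95% of their matched random lists on the TPM scale. Among genes chosen by the size of their ratio, Rpp40, a ribonuclease P subunit, had 209 counts in pool 1 and 2 in pool 2 (exact binomial adjusted p = 1.17e-59). In the other direction Lama3, a laminin chain, had 1 and 447 counts (exact binomial adjusted p = 1.48e-127), the lysosomal enzyme Arsb had 16.99 and 708, Tstd2 had 10.1 and 226, Zbed4 had 10 and 204 and the ubiquitin ligase Fancl had 15 and 210. With 1 library on each side these differences have no replicate check.

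**Figure D4:**
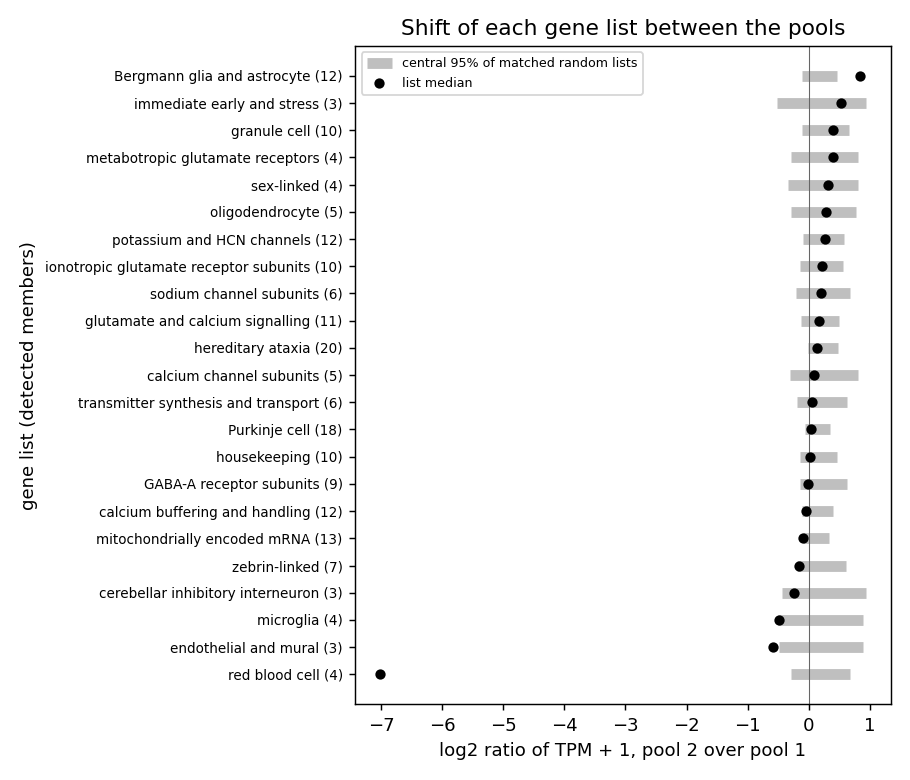
Median log2 ratio of TPM + 1, pool 2 over pool 1, of the detected members of each list (points; member numbers in brackets), with the central 95% of matched random lists as grey bars. The red blood cell list lies at -7.03 and the Bergmann glia and astrocyte list at 0.85. Under spike-in totals, which move all genes alike, the latter's median is -0.10, and 0.63 relative to all detected genes.

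Spike-in RNA held 0.211% of counts in pool 1 (exact 95% interval 0.209 to 0.213) and 0.411% in pool 2 (0.409 to 0.414), a ratio of 1.95. Of 96 spike-in transcripts, 31 had at least 1 count in pool 1 and 38 in pool 2. Over 34 with at least 10 counts in total the SD of the log2 ratio was 2.81, against 1.83 for genes of the same counts (central 95% of draws 1.22 to 2.502). At 100 counts or more it was 0.93 over 17 spike-ins, against 0.76 (0.44 to 2.02) for such genes.

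Most genes used the same main transcript in both pools. Over 1535 genes, 1438 (93.7%, exact 95% interval 92.3 to 94.8) had the same dominant transcript, whose median share of the gene's TPM was 92.4% ± 0.0731 (SD, n = 2). Pcp4 and Car8 have a single annotated transcript. Transcript Calb1-201 held 99.9% ± 0.00707 of Calb1, Gng13-201 held 86.7% ± 0.382 of Gng13 and Pcp2-203 held 59.4% ± 4.16 of Pcp2, followed by Pcp2-205 at 18.4% ± 1.04 and Pcp2-201 at 16.0% ± 2.94. Those are shares of TPM. Gng13-201 is short (347 bases), and it held 71.7% of the gene's counts in pool 1 and 72.7% in pool 2.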

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

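The rows with numeric identifiers, which name no gene and enter no comparison, held 129.7 expected counts in pool 1 and 55.6 in pool 2, above the 3 counts that a count of 0 allows. All of these counts lay on 4 of the 26248 rows, and no explanation was tested.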

How the results depend on the processing

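A value with no spread between pools was taken as unmoved only if unchanged at 3 significant digits, and either pool's TPM lies within 1 SD of a mean of 2 by construction. The mean count of detected genes was 13858 at a TPM of at least 0.1, 3659 at 5 and 12956 with at least 10 counts, and the count in both pools 12402, 3254 and 11836; in each pool alone the mean count was 7631 to 8421. The correlation was 0.920 with a pseudocount of 0.1, 0.979 with no filter, 0.958 at a TPM of at least 10, 0.959 for FPKM, 0.968 for posterior means and 0.959 without mitochondrially encoded genes. The coefficient of variation was 0.372 with DESeq2 size factors, 0.572 with no filter and 0.266 from 100 counts. The square root of the median of DESeq2's gene-wise dispersions, not a common dispersion, was 0.209. The number of genes differing between pools ran from 6774 of 9527 tested (71.1%, at least 100 counts in total) to 10911 of 14495 (75.3%, spike-in totals) over the alternatives run. The lowest share was 51.6%, with no filter on low counts (9493 of 18391). The Purkinje list's median was 8.09 for FPKM, 7.90 and 8.47 for the rescaled TPM (the latter chosen after seeing the data), 7.75 for posterior means and 7.76 to 7.78 in each pool alone. Its shift was -0.23 and the glial shift 0.65 in TMM-scaled counts on the log2(value + 1) scale. The median of the Purkinje list minus that of the red blood cell list reversed to -1.62 without replicate 2 and was 5.45 without replicate 1, since globin levels differed between pools. The SD of spike-in ratios was 0.934 from 100 counts, and centring them cannot move it. The dominant share was 89.97% at a TPM of at least 1 and 90.1% for posterior means, and 86.9% and 95.7% of genes kept 1 dominant transcript at a TPM of at least 1 and 100. Of the levels of named genes, 27 moved by more than the SD and 60 did not in the rescaled TPM, and 6 moved and 85 did not for posterior means. The shift of the mitochondrially encoded mRNA list in TMM-scaled counts and that of the microglial list for posterior means passed outside the range of random lists, and the endothelial shift fell inside it with no filter. The metallothionein shift reversed to -0.31 in count ratios under spike-in totals, an alternative chosen after seeing the data, which moves all genes alike. The shifts of the nuclear respiratory chain and ribosomal protein groups, positive on the TPM scale, were negative in count ratios under TMM, DESeq2 size factors and spike-in totals. Under total counts they stayed positive. The cause of the other changes was not tested.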

Other observations

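Of the tests in this part, those of globin copies, of vessel tissue and of a lower Purkinje share were chosen only after the results were seen, and so were the gene groups of this paragraph, defined by symbol. Nuclear genes of the respiratory chain and ATP synthase, 85 in number, had a median log2(TPM + 1) of 9.19 ± 0.04 (SD, n = 2), above all 10000 random lists, and 82 were detected in both pools. Ndufa4 (12401 ± 363), Cox6c (5762 ± 351), Ndufa3 (5687 ± 1148) and Atp5j (4587 ± 527) were the highest, and the group summed to a TPM of 106616 ± 5697. Cytosolic ribosomal protein genes, 79 in number, had a median of 7.78 ± 0.16 and were led by Rpl41 (2531 ± 197). The transcripts of both groups are short, so their TPM is raised by the effective lengths used. Ubiquitin and proteasome genes, 43 in number, had a median of 4.54 ± 0.05, with Ubb at 2185 ± 466, and a median log2 ratio, pool 2 over pool 1, of -0.02 (percentile 0.965 among matched random lists). The metallothioneins Mt1 (15172 ± 5327), Mt3 (1420 ± 330) and Mt2 (691 ± 312) had a median log2 ratio of 0.73 (percentile 99.4), which was -0.31 in count ratios under spike-in totals, or 0.42 relative to all detected genes. Glial markers moved the same way (0.85 in TPM, 0.63 relative to all detected genes). Mt2 and Mt3 are also on the second glial list described below, so this shift is not separate from the glial one. The shifts of the respiratory chain and ribosomal protein groups, 0.11 and 0.18 on the TPM scale, lay at percentiles 34.9 and 87.8. Their sign depended on the scaling. In count ratios they were -0.148 and -0.072 under TMM, 0.038 and 0.115 under total counts, and -0.928 and -0.852 under spike-in totals. Relative to all detected genes they were -0.19 and -0.11.

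Globin transcripts were far higher in pool 1. Reads moved between these globin copies are argued against, since all 4 globin genes were higher in pool 1. Their summed counts differed 156.5-fold (50519 against 334), which follows from those values and is no separate evidence. Red blood cells in pool 1 may be the source and stay open: a second red cell list, 11 of 12 genes measured, gave a depth-scaled ratio of 1.09 (exact 95% interval 0.956 to 1.25), but all but 3 and 1 of its counts were Bpgm. Vessel tissue also stays open: the 3 detected endothelial and mural markers had a median log2 ratio of -0.590 in TPM, short of the -1 set as the bound, and -1.27 in TMM-scaled count ratios, past it, and the spread allowed around that bound was defined only after the value was seen. No biological explanation was tested, since the design has 1 group.

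Glial markers were higher in pool 2 on the TPM scale. GC content or length bias is argued against, since the glial list lay above all matched random lists before and after both trends were removed. Its median log2 ratio was 0.85 before and 0.698 after (12 of 12 members had values). Those medians have different baselines. In the random lists drawn for this test, the central range was -0.107 to 0.460 before and -0.297 to 0.253 after. The fall in the median is therefore not a measure of how much GC content or length explained. A lower share of Purkinje RNA in pool 2 stays open. Markers of the other non-Purkinje types did not rise as glial markers did, with a median of -0.00135, or 0.08 without red blood cell genes. That median cannot decide, since 15 of 30 members were higher in pool 2 and the lists went both ways. Granule cell and oligodendrocyte markers had 0.40 and 0.29 (percentiles 73.3 and 58.1), endothelial and microglial markers -0.59 and -0.48 (percentiles 1.30 and 2.75). In count ratios the Purkinje list was at -0.27 relative to all detected genes. A candidate explanation is more glial RNA captured with pool 2: a second list of 20 glial genes had a median of 0.764, above all matched random lists, with 19 of 19 detected members higher, among them Mt3 (1420 ± 330), Cst3 (788 ± 318), Mt2 (691 ± 312) and Sparcl1 (686 ± 196). Some of these genes are not confined to glia. The second list is read on the same relative scale, so it cannot tell more glial RNA from less of other RNA. Under spike-in totals the first glial list had a median of -0.10, against -0.74 for all detected genes. The amounts of spike-in RNA are not given in the sources used here. No biological explanation was tested.

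The pseudogenes on chromosome 1 (24612775 to 24616197) were among the highest genes. Of the 31-base words in their 5 transcripts, 99.4% occur in annotated mitochondrial transcripts, so reads of mitochondrial RNA shared with the pseudogenes are a candidate explanation. No biological explanation was tested.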
